A study of Mus musculus with 6 samples.

How the data were processed

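Total RNA was measured in liver of 6 mice fed a high-fat diet for 8 weeks. Of these, 3 carried a hepatocyte-specific knockdown of Klf6, named DeltaHepKlf6 in the labels, and 3 were littermate controls. Each mouse gave 1 array, an Affymetrix mouse exon array read at the level of transcript probe sets, each a group of short probes that together report a transcript. Groups and replicate numbers were taken from the sample titles. The labels name separate mice, so the p-values of limma, fry and the permutations measure the spread between mice. Those of camera at the preset correlation compare a list's members with other genes, and they are too small where the members vary together between mice.

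The authors deposited 1 table of log2 values with 23332 probe sets and 6 arrays, rounded to 2 decimals, and per the submitters' processing notes Affymetrix Expression Console, RMA and limma were used, without versions, roles or order. RMA subtracts background, normalizes the arrays against each other and summarises the probes of a set, so values of dim probe sets lie close to background and differences of dim genes are compressed. That the deposited values are log2 was read from their range, 0.65 to 14.35, with array medians between 5.49 and 5.55. The genome build behind the probe sets is not given in the sources used here, and no coordinates are reported. No detection p-values or background signals were used here, so the share of probe sets above background is unknown, and the number of arrays limits the precision. No 2 arrays held identical values, and 0 sample columns were left unused.

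Gene names came from the platform annotation. Of the probe sets, 14996 named 1 gene, 1019 named several and 7317 had no gene name here. The gene identifiers of 14941 of the single-gene probe sets matched a RefSeq gene table, which changed 0 symbols. All 23332 probe sets were tested, and only single-gene probe sets were used to name a gene. Those sets cover 14860 genes. Where a gene had several such sets, the set with the highest mean over the 6 arrays stood for it in the list tests.

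DeltaHepKlf6 was compared with Control by lmFit and eBayes in limma 3.58.1 under R 4.3.3, on the log2 values as deposited, without a covariate, an intensity trend or a filter on dim probe sets. Differences are DeltaHepKlf6 minus Control on the log2 scale, with the standard error and 95% confidence interval of the moderated fit. P-values were adjusted by Benjamini-Hochberg over all probe sets, and a probe set was called at an adjusted p under 0.05. Of 37 gene lists for liver metabolism, stress, inflammation and cell types, 36 had at least 3 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, called at an adjusted p under 0.05 over the lists. The lists hold 624 genes, of which 489 were measured. Camera asks whether the members of a list shift relative to all other genes. The list tests were repeated with a correlation estimated for each list and with fry, which asks whether the members move one way on balance and compares them with no other genes, while its mixed form asks whether they move at all in either direction. Per-array values of lists and of the signal contrast were compared by two-sided exact permutation tests, for which 3 against 3 arrays allow no p below 0.1. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

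The groups, tests, lists, most other settings and the rule for named genes were fixed before the data were examined. By that rule the text names Klf6, the genes Ppara, Trib3 and Pck1 from published work on these mice, and up to 12 single-gene probe sets per direction. Places not filled by called probe sets went to the smallest unadjusted p among sets at least 1.5-fold different with no overlap between the groups. Predicted genes and members of families with near-identical copies were given as a count. Up to 4 members of each called list and up to 2 of every other list could be named, by unadjusted p. Other genes named in the text were chosen after their values were seen, and are given to describe a list or an array.

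The fit was tested on simulated data, arrays with the real means of the 23332 probe sets and their spreads as moderated by limma, 3 arrays against 3. It recovered 14% of 100 changes of 1 on the log2 scale and 83% of 100 changes of 2, and called 3 unchanged probe sets. With 2 lists shifted by 0.5, camera recovered 2 and fry 2, with 1 other list called by fry, and camera with an estimated correlation recovered 1. The simulated genes varied independently of each other, unlike real lists such as the macrophage markers, with an estimated correlation of 0.548. The simulation therefore cannot rank these methods for lists whose members vary together.

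The other settings chosen in advance were an intensity trend with robust hyperparameters, leaving out the dimmest 25% or 50% of probe sets, quantile normalization, equal array medians, array weights, the replicate number as a block, a Student test per probe set, other thresholds, the mean of all probe sets of a gene in the lists, and leaving out each array in turn. After the data were seen, a fit on probe sets with a gene name and a fit with the signal contrast of each array as a covariate were added. That contrast is the mean of probe sets with a gene name minus the mean of those without, on the log2 scale.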

Results

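Liver RNA of 6 mice was profiled on exon arrays after 8 weeks of a high-fat diet. In 3 of them Klf6 had been knocked down in hepatocytes only (DeltaHepKlf6), and 3 were littermate controls. Klf6 encodes a zinc finger transcription factor of the Kruppel-like family. Per the labels, the controls were glucose intolerant with marked fat in the liver, and the DeltaHepKlf6 mice had better glucose tolerance and less fat. The comparison was made to look for genes downstream of Klf6 in glucose and lipid metabolism. Array medians lay between 5.49 and 5.55 on the log2 scale, and pairs of arrays correlated across probe sets with 0.961 to 0.973 among controls, 0.957 to 0.971 among DeltaHepKlf6 and 0.953 to 0.974 between the groups.

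Klf6 was read first in every array. Its value was 6.80, 6.09 and 5.88 in Control 1, 2 and 3, and 5.93, 5.43 and 5.45 in DeltaHepKlf6 1, 2 and 3. The mean was 6.26 ± 0.48 (SD, n = 3) in Control and 5.60 ± 0.28 (SD, n = 3) in DeltaHepKlf6, a log2 difference of -0.65 with a standard error of 0.28 and a 95% confidence interval of -1.34 to 0.03. This did not pass the test (limma, unadjusted p = 0.0587, Benjamini-Hochberg adjusted p = 0.998), and DeltaHepKlf6 1 lay above Control 3. Without Control 1 the difference was -0.38. Whole liver also holds cells in which the gene was not targeted, and which exons the probe set covers is not given in the sources used here.

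In the same livers, the markers of macrophages and Kupffer cells, the resident macrophages of the liver, were lower in DeltaHepKlf6 in 16 of 16 measured members, with a median log2 difference of -0.41. The list of acute phase proteins, most of them secreted by hepatocytes in inflammation, was lower in 15 of 17 members. Genes of glycolysis and glycogen metabolism were lower in 9 of 11, genes of endoplasmic reticulum stress in 17 of 19, and genes of fibrosis and extracellular matrix in 16 of 18. Genes known for higher expression in female liver were higher in 6 of 9 members. Over all 14860 genes the mean log2 difference was -0.06 and the median -0.05, so list means near these values are those of genes in general. For bright genes this reference was lower. Random lists matched to the macrophage markers on mean expression had a typical median of -0.083. Camera called these 6 of 36 lists, 5 lower and 1 higher, and 0 of the 36 were called with an estimated correlation, where the smallest adjusted p was 0.965 and 1 list had an unadjusted p under 0.05, or by fry, where the smallest adjusted p was 0.714 and 0 lists had an unadjusted p under 0.05. No single member of any list passed limma's test, with 0 members adjusted over all genes and 0 adjusted over the list alone in each list.

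**Figure D1:**
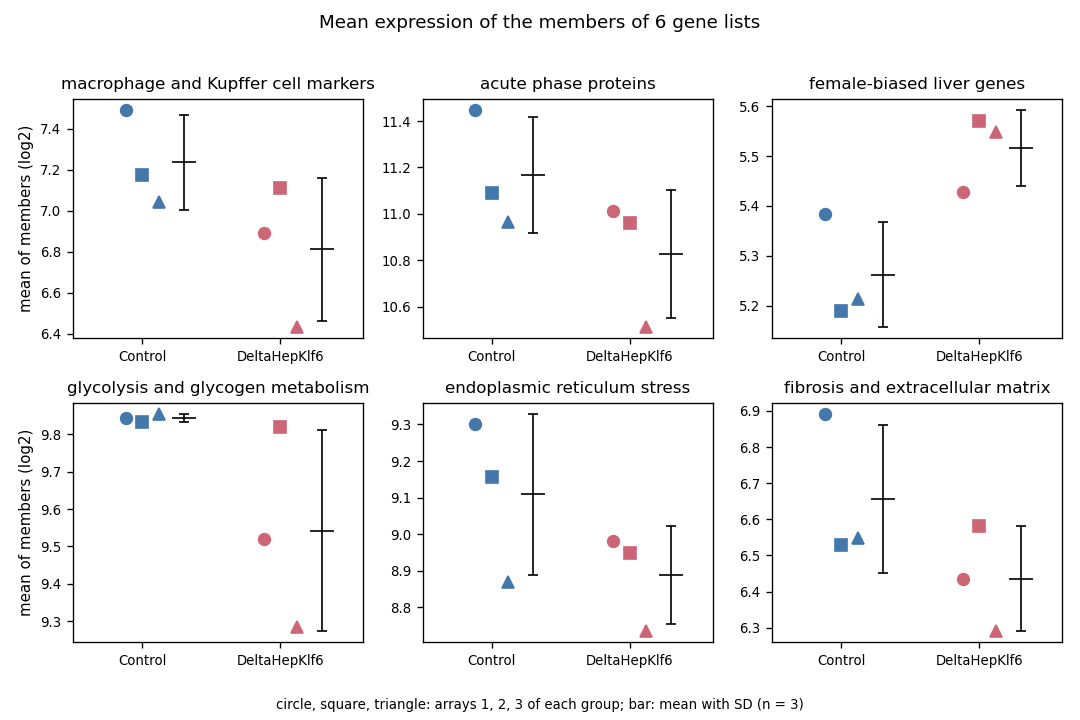
Mean log2 value of the members of the 6 called gene lists in each array, with circles, squares and triangles for arrays 1, 2 and 3 of each group and a bar for the mean with SD (n = 3). The macrophage and Kupffer cell score was 7.24 ± 0.23 in Control and 6.81 ± 0.35 in DeltaHepKlf6, and the groups overlapped in this score, with DeltaHepKlf6 2 above Control 3 (exact permutation p = 0.2).

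Across all probe sets, limma called 0 of 23332 at an adjusted p under 0.05, 0 higher and 0 lower in DeltaHepKlf6, and 0 at an adjusted p under 0.10. Without the variance shared between probe sets in limma, the same adjustment also called 0. At an unadjusted p under 0.05, limma counted 750 probe sets, 375 higher and 375 lower, which is 3.21% of those tested, where chance alone would give 1166.6. Without DeltaHepKlf6 2 that count was 1797, and without any other single array between 674 and 799. At an unadjusted p under 0.01 it counted 143, where chance would give 233.3. The 3 values of one group lay clear of the 3 of the other in 1567 probe sets or 6.72%, 856 lower and 711 higher, and chance gives 10%. In simulation this design recovered 14% of changes of 1 and 83% of changes of 2 on the log2 scale. The simulated probe sets varied independently, so these rates need not hold for the real arrays, where probe sets can vary together.

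Among single-gene probe sets, 72 were lower and 53 higher in DeltaHepKlf6 by at least 1.5-fold without overlap between the groups, and none of them passed the test. The lower set with a name included Cd74, the invariant chain of MHC class II, with 7.32 ± 0.20 in Control and 6.22 ± 0.39 in DeltaHepKlf6 (SD, n = 3) and a log2 difference of -1.11 with a standard error of 0.23. It also included Herpud1, a gene of endoplasmic reticulum protein degradation, with -0.63 ± 0.14 (SE), and Plekhf1, with -1.07 ± 0.28 (SE). Cpe, the processing enzyme carboxypeptidase E, differed by -0.71 ± 0.17 (SE), the palmitoyltransferase gene Zdhhc7 by -0.66 ± 0.17 (SE) and the aldo-keto reductase gene Akr1b10, a dim probe set with a mean of 3.54 in Control, by -0.65 ± 0.15 (SE), while the other probe set of Akr1b10 differed by -0.003 ± 0.211 (SE). On the higher side stood Chrm2, a muscarinic acetylcholine receptor, with 3.86 ± 0.315 in Control and 5.20 ± 0.10 in DeltaHepKlf6 (SD, n = 3) and a log2 difference of 1.34 with a standard error of 0.19. The transcription factor genes Twist1, with 0.67 ± 0.16 (SE), and Zfp281, with 0.63 ± 0.18 (SE), and the zinc finger gene Zcchc13, with 0.65 ± 0.16 (SE), completed the named places. Chrm2, Twist1 and Zcchc13 were dim as well. Their Control means of 3.86, 4.72 and 4.93 lay below 5.788, the median over probe sets with a gene name. Cpe and Zdhhc7, with Control means of 5.71 and 5.64, lay slightly below that median too. A further 6 lower and 8 higher places went to olfactory or vomeronasal receptors, predicted genes or members of other families with close copies. For Cd74, Herpud1, Chrm2 and the others in this paragraph, limma's Benjamini-Hochberg adjusted p was 0.998.

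**Figure D2:**
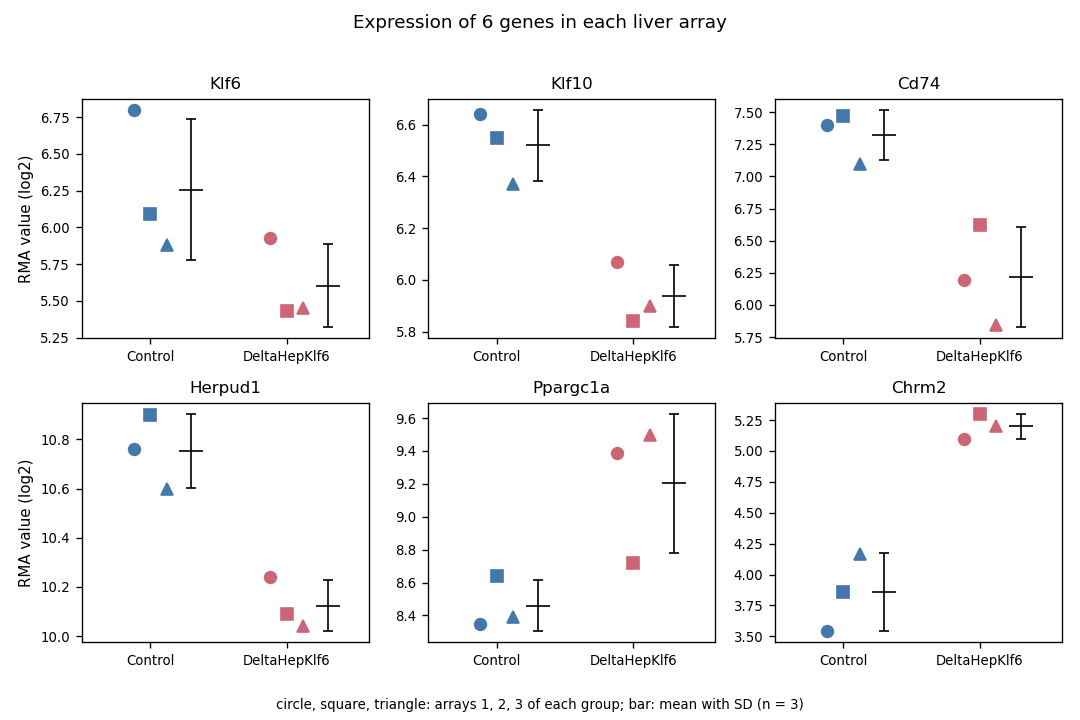
Log2 values of Klf6, Klf10, Cd74, Herpud1, Ppargc1a and Chrm2 in each array, with circles, squares and triangles for arrays 1, 2 and 3 of each group and a bar for the mean with SD (n = 3). In the Klf6 panel DeltaHepKlf6 1 (5.93) lies above Control 3 (5.88), while the groups do not overlap for the other genes, and none of the 6 passed the test.

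Within the macrophage and Kupffer cell list, Clec4f, a lectin of Kupffer cells, had a log2 difference of -0.78 ± 0.33 (SE), Cd163, a scavenger receptor, of -0.51 ± 0.20 (SE), Cd5l of -0.49 ± 0.21 (SE) and Timd4, a receptor of resident macrophages, of -0.48 ± 0.215 (SE). Without DeltaHepKlf6 3 the differences of Clec4f, Cd5l and Timd4 were -0.49, -0.31 and -0.27. These 4 members had no overlap between the groups, and 1 of the 16 members had an unadjusted p under 0.05. Vsig4 differed by only -0.09 ± 0.18 (SE). Camera gave an adjusted p = 5.07e-06 with the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation. Leaving out DeltaHepKlf6 3, the array with the lowest score, brought the mean difference from -0.42 to -0.23, and camera at the preset correlation still called it with each array left out in turn and with the signal contrast as a covariate (camera adjusted p = 1.95e-05). Endothelial cell markers had a mean difference of -0.10 with 10 of 13 members lower, and stellate cell markers of -0.11 with 8 of 12 lower, and neither list was called by camera (unadjusted p = 0.361 and 0.426). Without Control 1 these means were -0.03 and -0.02, and without DeltaHepKlf6 3 0.01 and -0.08. The signal contrast of the arrays was 1.20, 0.99 and 0.90 in Control 1, 2 and 3 and 0.80, 1.19 and 0.76 in DeltaHepKlf6 1, 2 and 3 (exact permutation p = 0.5, where 0.1 is the smallest possible), and the macrophage score was lowest in the array of lowest contrast.

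Other immune lists held mostly lower members and were not called without a block or covariate while all 6 arrays were used. Neutrophil markers were lower in 9 of 11 members with a mean of -0.41 (camera adjusted p = 0.0866), and their mean level was 5.75 in Control 1 against 5.18 and 4.91 in Control 2 and 3. Without Control 1 the difference was -0.17. The list was called without Control 3 or DeltaHepKlf6 1 and with the replicate number as a block (camera adjusted p = 0.0219, 0.0379 and 0.00103), against an adjusted p = 0.965 with an estimated correlation on all arrays. Cytokines and receptors of inflammation were lower in 16 of 20 members with a mean of -0.24 (camera adjusted p = 0.108), which was -0.14 without Control 1 or DeltaHepKlf6 3. They were called without Control 3 or DeltaHepKlf6 1 and with the block (camera adjusted p = 0.00306, 0.0252 and 0.0229), against an adjusted p = 0.965 with an estimated correlation. T and NK cell markers were lower in 10 of 14 with a mean of -0.12 (camera adjusted p = 0.383), from -0.04 without Control 2 to -0.23 without Control 1. They were called without Control 1 and with the signal contrast as a covariate (camera adjusted p = 0.00047 and 0.0428), against an adjusted p = 0.965 with an estimated correlation. Cxcl10, a chemokine, differed by -0.81 ± 0.39 (SE) and Csf3r, the receptor of the granulocyte growth factor, by -0.41 ± 0.17 (SE), and without Control 1 by -0.44 and -0.27. B cell and plasma cell markers had a mean of -0.08 and the interferon response of -0.09 (camera adjusted p = 0.934 and 0.660). The B cell mean ranged from -0.007 without DeltaHepKlf6 1 to -0.135 without DeltaHepKlf6 2. The interferon list was called without DeltaHepKlf6 1 (camera adjusted p = 0.0357, mean of -0.23), against an adjusted p = 0.965 with an estimated correlation. Immediate early genes, which respond within minutes to stress or growth factors, were lower in 11 of 13 members with a mean of -0.31 (camera adjusted p = 0.0664), and their mean over members was 7.27 in Control 1 against 6.35 and 6.28 in Control 2 and 3. Without Control 1 their mean difference was 0.005. They were called without Control 2, Control 3 or DeltaHepKlf6 1 and with the block (camera adjusted p = 0.00927, 0.00215, 0.0451 and 0.0229), against an adjusted p = 0.965 with an estimated correlation of 0.709 between members.

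Acute phase proteins had a mean log2 difference of -0.34. Steap4, a metalloreductase, differed by -0.77 ± 0.34 (SE) and by -0.47 without Control 1, Apcs, serum amyloid P, by -0.40 ± 0.17 (SE), Hpx, the heme carrier hemopexin, by -0.38 ± 0.20 (SE), or -0.25 without DeltaHepKlf6 3, and Itih3 by -0.31 ± 0.15 (SE), while the fibrinogen genes Fga, Fgb and Fgg differed by -0.05, -0.01 and 0.02. Camera's adjusted p was 0.00443 at the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation. Without DeltaHepKlf6 2 the preset call ended (camera adjusted p = 0.0891), although the mean difference was larger, -0.40. The mean was -0.18 without DeltaHepKlf6 3 and -0.20 without Control 1, where the list was still called (camera adjusted p = 0.0311 and 0.0224). With the signal contrast as a covariate the mean was -0.24, and the list was called at the preset correlation (camera adjusted p = 0.0051).

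Genes of glycolysis and glycogen metabolism had a mean log2 difference of -0.30 and a median of -0.39. The mean over members was 9.84, 9.83 and 9.85 in Control 1, 2 and 3. It was 9.52, 9.82 and 9.28 in DeltaHepKlf6 1, 2 and 3, so DeltaHepKlf6 2 lay close to the controls. Without DeltaHepKlf6 2 the mean difference was -0.44. Gckr, a regulatory protein of glucose use in hepatocytes, was 9.23 ± 0.15 in Control and 8.75 ± 0.09 in DeltaHepKlf6 (SD, n = 3), a difference of -0.48 ± 0.14 (SE) without overlap. Pygl, glycogen phosphorylase, differed by -0.39 ± 0.20 (SE), Ppp1r3b, a subunit that directs a phosphatase to glycogen, by -0.39 ± 0.22 (SE) and Slc2a2, the glucose transporter of hepatocytes, by -0.27 ± 0.15 (SE), whereas Gys2, glycogen synthase, differed by 0.04 ± 0.17 (SE). Without DeltaHepKlf6 3 Pygl and Slc2a2 differed by -0.24 and -0.17, and without DeltaHepKlf6 1 Ppp1r3b by -0.21. Camera's adjusted p was 0.0105 at the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation. The preset call ended with quantile normalization (camera adjusted p = 0.0733, mean of -0.22) and without Control 2, Control 3 or DeltaHepKlf6 3 (camera adjusted p = 0.0506, 0.0603 and 0.0545), with mean differences of -0.31, -0.29 and -0.17. With the signal contrast as a covariate the mean was -0.22, and the list was called at the preset correlation (camera adjusted p = 0.01055).

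Genes of endoplasmic reticulum stress had a mean log2 difference of -0.22, led by Herpud1, with Hyou1 at -0.54 ± 0.26 (SE), or -0.31 without DeltaHepKlf6 3, Sesn2 at -0.41 ± 0.21 (SE) and Pdia4 at -0.34 ± 0.20 (SE). Ddit3, a transcription factor of the stress response, stood on the other side with 0.38 ± 0.18 (SE). Camera's adjusted p was 0.0105 at the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation. The preset call ended without Control 1, Control 2, DeltaHepKlf6 2 or DeltaHepKlf6 3 (camera adjusted p = 0.0543, 0.170, 0.296 and 0.0545), and the mean difference ranged from -0.34 without Control 3 to -0.13 without Control 1, with -0.14 without DeltaHepKlf6 3 and -0.25 without DeltaHepKlf6 2. With the signal contrast as a covariate the mean was -0.16, and the list was called at the preset correlation (camera adjusted p = 0.0115).

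Fibrosis and extracellular matrix genes also had a mean of -0.22. Sparc, a matrix glycoprotein, was 10.53 ± 0.15 in Control and 10.02 ± 0.32 in DeltaHepKlf6 (SD, n = 3), and Acta2, smooth muscle actin, differed by -0.85 ± 0.35 (SE). Without DeltaHepKlf6 3 Sparc and Acta2 differed by -0.34 and -0.53. Thbs1 differed by -0.77 ± 0.46 (SE), with 7.23 in Control 1 against at most 5.64 in every other array and a difference of -0.22 without Control 1, and Col6a1 by -0.25 ± 0.15 (SE). Lum, lumican, was on the other side with 0.38 ± 0.19 (SE). Camera's adjusted p was 0.0195 at the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation. The preset call ended without Control 1, where the mean was -0.10 (camera adjusted p = 0.247), without DeltaHepKlf6 2 or DeltaHepKlf6 3 (camera adjusted p = 0.0880 and 0.0545; means of -0.29 and -0.15), without the dimmest 50% of probe sets (camera adjusted p = 0.0590), where the mean of -0.23 was no smaller, and with the signal contrast as a covariate (camera adjusted p = 0.0793), where it was -0.13.

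The list of genes known for higher expression in female liver had a mean log2 difference of 0.25 and a median of 0.11. Its largest members rested on single arrays. Acot3, an acyl-CoA thioesterase that is also on the list of PPAR alpha targets, differed by 0.82 ± 0.38 (SE) and by 0.37 without DeltaHepKlf6 3, and Cyp17a1, a steroid hydroxylase, by 0.68 ± 0.535 (SE) and by 0.09 without Control 2. Fmo2, a flavin monooxygenase, differed by 0.45 ± 0.20 (SE) and Sult3a1, a dim probe set, by 0.34 ± 0.25 (SE), with Fmo2 at 0.28 without Control 1 and Sult3a1 at 0.09 without DeltaHepKlf6 2. Camera's adjusted p was 0.00955 at the preset correlation. The list had an adjusted p = 0.965 with an estimated correlation, where its unadjusted p was 0.0325. The preset call ended with quantile normalization (camera adjusted p = 0.0661), although the mean of 0.28 was no smaller. It held with each array left out in turn, with means from 0.22 without Control 2 to 0.31 without Control 1. It also held with the signal contrast as a covariate (camera adjusted p = 0.01055, mean of 0.29). Genes known for higher expression in male liver were lower in 7 of 7 members with a mean of -0.17 (camera adjusted p = 0.363), which was -0.002 without DeltaHepKlf6 3 and -0.07 without Control 1. The Y-linked genes Eif2s3y and Kdm5d, too few to test as a list, lay between 8.85 and 9.17 and between 6.65 and 7.37 over the 6 arrays.

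For the genes named in published work on these mice, the log2 difference was -0.13 ± 0.13 (SE) for Ppara, a receptor that controls fatty acid breakdown, 0.02 ± 0.15 (SE) for Trib3, a pseudokinase linked to insulin signalling, and 0.00 ± 0.14 (SE) for Pck1, an enzyme of glucose synthesis, with a camera adjusted p = 0.963 for the 3 as a list. That list was drawn from earlier work on these mice and is no independent evidence. Targets of PPAR alpha had a mean of -0.05 with 10 of 17 members lower, 0.005 above the mean of other genes, and mitochondrial fatty acid oxidation of -0.15 with 13 of 16 lower (camera adjusted p = 0.940 and 0.176). Slc25a20, the carnitine carrier, differed by -0.60 ± 0.23 (SE). Without DeltaHepKlf6 3 the mean of fatty acid oxidation was -0.06. Synthesis of fatty acids and triglycerides had a mean of -0.14 with 15 of 20 lower, and genes of lipid droplets and lipid uptake of -0.09 with 16 of 20 lower (camera adjusted p = 0.331 and 0.685). Without DeltaHepKlf6 3 these means were -0.03 and 0.05, and without Control 1 -0.06 and 0.01. Within the list of lipid droplets, G0s2, an inhibitor of the main triglyceride lipase, differed by 0.68 ± 0.28 (SE) and Fitm1, a protein of lipid droplet formation, by -0.42 ± 0.17 (SE), both without overlap, with G0s2 at 0.38 without Control 1. Ppargc1a, a coactivator that drives glucose synthesis and fatty acid oxidation, was 8.46 ± 0.16 in Control and 9.20 ± 0.42 in DeltaHepKlf6 (SD, n = 3), a difference of 0.74 ± 0.24 (SE) without overlap, while its list of glucose synthesis and amino acid breakdown had a mean of -0.07 (camera adjusted p = 0.940). Within the Kruppel-like family, with a mean of -0.07 (camera adjusted p = 0.685), Klf10 was 6.52 ± 0.14 in Control and 5.94 ± 0.12 in DeltaHepKlf6 (SD, n = 3), a difference of -0.58 ± 0.14 (SE), and Klf7 differed by -0.33 ± 0.16 (SE), or -0.19 without Control 1. For each of these genes limma's Benjamini-Hochberg adjusted p was 0.998.

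The other metabolic and regulatory lists were not called either. Targets of NRF2, the regulator of antioxidant genes, had a mean of -0.21 with 12 of 14 lower, among them Hmox1, heme oxygenase, at -0.83 ± 0.34 (SE), or -0.53 without DeltaHepKlf6 3, and Pgd at -0.69 ± 0.26 (SE) (camera adjusted p = 0.133). Their mean was -0.08 with the signal contrast as a covariate, -0.07 without DeltaHepKlf6 3 and -0.37 without DeltaHepKlf6 2. In the last case the list was called (camera adjusted p = 0.0219), against an adjusted p = 0.965 with an estimated correlation on all arrays. Bile acid synthesis and transport had a mean of -0.06 with Abcc3, an efflux pump, at -0.51 ± 0.18 (SE), insulin signalling of -0.13, xenobiotic metabolism of -0.08, autophagy of -0.11, oxidative phosphorylation of -0.10 and the circadian clock of -0.06, with bile acid and clock genes within 0.004 of the mean of other genes. Cholesterol synthesis had a mean of -0.01 with camera's shift upward relative to other genes, and the cell cycle list a mean of -0.001, a median of 0.008 and the same upward shift. Without DeltaHepKlf6 3 the mean was -0.005 for bile acids, -0.04 for insulin signalling and 0 for xenobiotic metabolism. The camera adjusted p for these lists after NRF2 lay between 0.331 and 0.940. Hepatocyte markers had a mean of -0.08 (camera adjusted p = 0.849), cholangiocyte markers of 0.10 (0.331), adipocyte markers of -0.003 (0.940) and erythroid markers of -0.05 (0.940). For adipocyte and erythroid markers camera's direction was upward against a mean below 0.

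Markers of exocrine pancreas, the tissue that makes digestive enzymes, were high in 1 array. Cela1, an elastase, was at 12.15 in Control 3 and between 6.01 and 6.64 in the other 5 arrays, Ctrb1 at 12.45 against 5.32 to 5.71, Cpa1 at 11.26 against 4.40 to 4.64 and Clps at 12.05 against 6.39 to 6.81. Skeletal muscle markers showed no such gap, with Ckm at 6.38 in Control 3 and 6.16 to 6.34 elsewhere. The list of pancreas and muscle markers had a mean log2 difference of -1.21 (camera adjusted p = 0.0997), and without Control 3 of 0.03, while it was called without Control 1 or Control 2 and with the signal contrast as a covariate (camera adjusted p = 0.00239, 0.00927 and 0.0211), against an adjusted p = 0.965 with an estimated correlation. Control 3 entered every fit, and without it limma again called 0 probe sets, and camera called 8 lists, 5 of them among the 6 above.

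**Figure D3:**
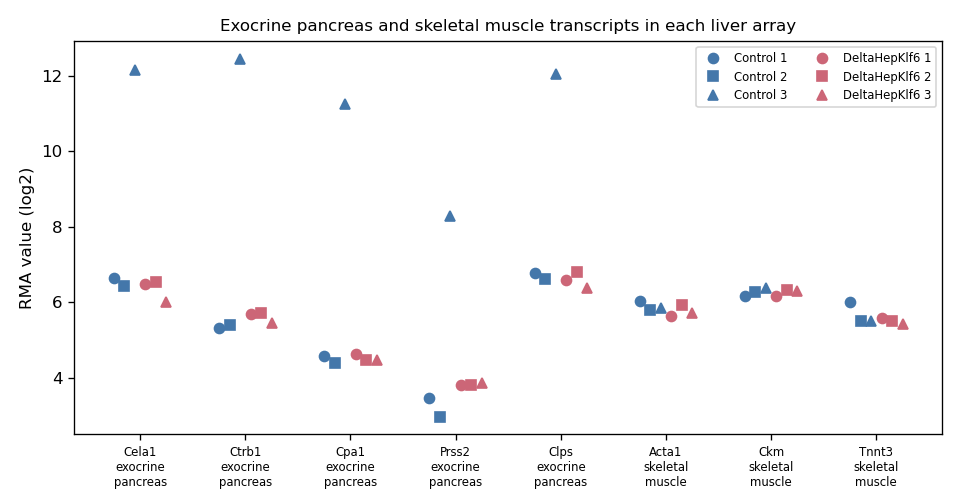
Log2 values of 5 exocrine pancreas and 3 skeletal muscle transcripts in each of the 6 liver arrays, blue for Control and red for DeltaHepKlf6, with circles, squares and triangles for arrays 1, 2 and 3. Control 3 stands more than 4 log2 units above every other array for each pancreas transcript, the smallest gap being 4.41 for Prss2.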

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

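The fit on probe sets with a gene name and the fit with the signal contrast as a covariate were chosen after the data were seen. The count of 0 called probe sets held under every alternative run, except that the looser rule of unadjusted p under 0.01 and at least 1.5-fold, which has no correction for multiple tests, gave 132, 76 higher and 56 lower. Klf6 stayed lower and not called under each, from -0.84 without Control 3 to -0.38 without Control 1. Lists called numbered 6, against 0 with an estimated correlation and 0 by fry, and ran from 3 without DeltaHepKlf6 3 to 10 without DeltaHepKlf6 1. The estimated correlation changes the correlation allowed between genes. It also makes camera use the residual degrees of freedom of the fit, not those from the number of genes, which raises p-values. Genes higher in female liver had an estimated correlation of 0.022, near the preset 0.01, yet their unadjusted camera p went from 0.000796 to 0.0325. The lost calls therefore cannot be put down to correlation between members alone. Fry also asks another question, and the cause of the other changes was not tested. The labels do not say that equal replicate numbers pair mice. Deviations from the group means correlated with -0.13, -0.17 and 0.21 for equal numbers. Deviations of 3 arrays around their own mean are not independent, so these values cannot exclude a pairing. With the number as a block, 0 probe sets and 9 lists were called, the additions being neutrophil markers, inflammatory cytokines and immediate early genes, and Klf6 differed by -0.65. Of 96 named genes, 0 passed in any of 1228 alternative values, and 6 turned sign at least once. Trib3 was -0.012 with array weights and -0.014 with the covariate, and Pck1 -0.014 with array weights. Leaving out each array in turn gave ranges of -0.08 to 0.13 for Trib3, -0.09 to 0.055 for Pck1, -0.06 to 0.77 for Mmp7, -0.013 to 0.303 for Klf1, -0.008 to 0.152 for Eif2s3y and -0.132 to 0.228 for Kdm5d. Mean differences of lists also turned sign, most of them lists near 0, and the cause was not tested. With quantile normalization they were 0.009 for the genes from published work, 0.002 for PPAR alpha targets, 0.051 for cholesterol synthesis, 0.007 for the cell cycle, 0.007 for the circadian clock and 0.012 for adipocyte markers. With the covariate they were 0.054 for cholesterol synthesis, 0.002 for glucose synthesis and amino acid breakdown, 0.019 for the cell cycle, 0.009 for oxidative phosphorylation and 0.015 for erythroid markers. Over the arrays left out, list means ranged from -0.078 to 0.007 for the genes from published work, -0.122 to 0.044 for PPAR alpha targets, -0.153 to 0.047 for lipid droplets, -0.138 to 0.086 for cholesterol synthesis, -0.139 to 0.011 for glucose synthesis, -0.491 to 0.005 for immediate early genes, -0.234 to 0.027 for the interferon response, -0.193 to 0.005 for autophagy, -0.039 to 0.045 for the cell cycle, -0.217 to 0.014 for oxidative phosphorylation, -0.187 to 0.012 for endothelial, -0.088 to 0.251 for cholangiocyte, -0.101 to 0.061 for adipocyte, -0.14 to 0.029 for erythroid and -1.879 to 0.027 for pancreas and muscle markers, the last value being that without Control 3, which alone holds the pancreas transcripts. Immediate early genes turned without Control 1, where they were highest. Scaling moved the median difference of all probe sets from -0.037 to -0.012 with quantile normalization. Signal over background is not known for these arrays, so differences of dim genes such as Sult3a1 and Akr1b10 may be understated by compression. They may also be overstated, since these genes were named for a small p. Leaving out the dimmest 50% of probe sets called 5 lists.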

Other observations

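The MHC class II genes, the pancreas transcripts beyond the preset markers, the comparison of macrophage with endothelial and stellate markers, the comparison of genotypes without Control 3 and the test for pancreas tissue were chosen after the result was seen, while the other tests in this part were written before theirs. For MHC class II genes with the signal contrast and for the genes next to Klf6, the values met the criteria written in advance against these explanations. Both criteria were made stricter after the values were seen, because neither value exceeded its spread, which left both questions open.

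Cd74 was not the only gene of MHC class II antigen presentation with lower values in DeltaHepKlf6. H2-Aa was 8.68 ± 0.41 in Control and 7.54 ± 0.49 in DeltaHepKlf6 (SD, n = 3), a log2 difference of -1.14 with a standard error of 0.32. H2-Ab1 differed by -0.73 ± 0.34 (SE), H2-DMa by -0.56 ± 0.17 (SE) and H2-Oa by -0.31 ± 0.28 (SE). The difference of H2-Oa rested on DeltaHepKlf6 3, at 3.73, with DeltaHepKlf6 1 and 2 at 4.80 and 4.43 and Control at 4.53 to 4.69. H2-Ab1 was highest in Control 2, at 8.62 against 7.94 and 7.59 in Control 1 and 3. The mean over these 5 genes was 6.74, 7.08 and 6.57 in the controls and 6.05, 6.37 and 5.66 in DeltaHepKlf6, a difference of -0.77 without overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows). It ranged from -0.94 without DeltaHepKlf6 2 to -0.59 without DeltaHepKlf6 3. None of the 5 passed limma's test (Benjamini-Hochberg adjusted p = 0.998), and the genes were picked because they were low.

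The macrophage score (exact permutation p = 0.2) and the MHC class II genes were lower together. A lower share of all non-parenchymal cells is argued against over members, since endothelial and stellate markers lay at least 4.09 standard errors above the macrophage markers, but genes of a list are not independent. Per array, the macrophage score minus the endothelial score was -0.37 ± 0.11 in Control and -0.69 ± 0.14 in DeltaHepKlf6 (SD, n = 3; exact permutation p = 0.1, the smallest possible), and minus the stellate score -0.04 ± 0.14 and -0.36 ± 0.28 (exact permutation p = 0.2, with overlap). DeltaHepKlf6 3 carried much of the stellate gap, at -0.68 against -0.24 and -0.16 in DeltaHepKlf6 1 and 2. With the signal contrast as a covariate the macrophage mean kept 0.657 of its size (-0.28, 95% confidence interval -0.76 to 0.21), below the 0.8 set in advance. The MHC class II mean kept 0.856 (-0.66, -1.43 to 0.11), which met the 0.8, but both intervals hold 0. Of 10000 random lists matched on mean expression, 0% reached the macrophage median of -0.41, and 0% the MHC class II median of -0.73. Such lists lack the correlation between members, 0.548 for macrophage genes. They were also not chosen for low values. The MHC class II genes were picked because they were low, so their 0% followed from that choice and tests nothing. The macrophage list was taken up here because camera had already called it lower. An array effect therefore stays open for both. Markers of dendritic cells and monocytes differed by -0.027 with a standard error of 0.071 over 9 members, but their median level of 5.29 is below the 5.83 of all genes, so fewer such cells may still contribute.

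Control 3 held 24 single-gene probe sets more than 4-fold above every other array, against 0 to 2 in the others, and the 5 highest excesses were those of Cpb1 (11.85 against at most 4.21), 2210010C04Rik, Zg16, Ctrb1 and Cpa1. Carry-over of exocrine pancreas into that liver sample is a candidate explanation, as 5 of 5 preset exocrine markers were more than 2 log2 units above every other array and 0 of 3 muscle markers were. Islet tissue is left open, since 1 of 10 islet genes, Ins2, was more than 0.5 above every other array, with an excess of 0.59. A difference between the genotypes is argued against, because the median of 12 exocrine genes in Control 1 and 2 differed from DeltaHepKlf6 by -0.052. That pancreas RNA, rich in endoplasmic reticulum transcripts, made the endoplasmic reticulum stress list lower in DeltaHepKlf6 is also argued against, as the mean difference without Control 3 was 1.541 times that with all arrays (-0.34 against -0.22).

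DNA of the founder strain that flanks a targeted locus could make neighbouring genes differ whatever Klf6 does. The 50 measured genes nearest Klf6 in the RefSeq order of assembly GRCm38.p6, 15 before and 35 after because only 15 lie on that side, had a mean absolute t of 0.685, and 83.1% of 13779 windows of 50 genes elsewhere had at least as much. The standard error of 0.083 over these genes reaches the median window at 0.767, so the test leaves a small effect open. Among these genes, 1 had an unadjusted p under 0.05 in limma, Akr1c19, with a log2 difference of 0.62.

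The 10 ways to split the 6 arrays into 3 and 3 are too few for a share under 0.05. At an adjusted p under 0.05 the real count is 0, which all 10 reach by construction, so this count tests nothing, and the highest other was 1. For an unadjusted p under 0.05, 6 gave at least the real 750, the highest other being 2656. For lists called by camera at the preset correlation, 3 gave at least the real 6, the highest other being 8. The split with 2656 set Control 1, Control 2 and DeltaHepKlf6 2 against the rest, and the split of Control 1, Control 3 and DeltaHepKlf6 2 gave 2324. Counts several times the real one point to a structure of the samples that the genotype does not follow, and Control 1, Control 2 and DeltaHepKlf6 2 are the arrays with the highest signal contrast. The first principal component, the main axis of variation between the arrays, held 37.1% of the variance. Its Pearson correlation with the signal contrast over the 6 arrays was -0.9935.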
